A study of Mus musculus with 8 samples.

How the data were processed

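Total RNA was taken, per the labels' protocols, from primary hepatic stellate cells at passage 0, isolated from IL15Ra-knockout and wild-type mice of a mixed background by perfusing the liver with pronase and collagenase, followed by a Percoll density gradient, and kept in medium with serum. The labels call the mice female, but Y-linked probes were above background on all arrays, as described at the end. Each of the 8 samples, 4 IL15Ra-knockout and 4 control, was hybridised to 1 array of the Illumina MouseRef-8 v2.0 BeadChip, a 1-colour platform with bead-bound probes. The group of each sample came from the titles and genotype labels, and the replicate number from the title. The labels do not say that the 4 samples of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical.

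The deposited table gives for each probe and array a mean bead signal, an intensity on a linear scale that is neither normalised nor background-subtracted, per the file headers and the values. Beside it stands a detection p-value, deposited per probe and array, that sets the probe against the negative-control beads of that array. The authors read the scans with GenomeStudio, listed as version 3 in the submitters' processing notes. A second deposited table holds intensity values that the authors quantile normalised between the 8 arrays, per the series' design text, on a linear scale, and its columns had medians between 126.0 and 126.4 and ranked the probes like the unnormalised signals of the same sample, with a Spearman coefficient of at least 0.999996. Neither table gave control probes or chip positions, so no chip could be tested as a batch. Of the 25697 probes, 23978 had 1 gene symbol in the platform annotation, 0 had several and 1719 are unnamed here. Symbols were looked up by Entrez number in the GRCm38.p6 gene table, which changed 0 of them.

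Signals were background corrected and quantile normalised with neqc of limma 3.58.1 in R 4.3.3, which takes the negative-control moments from the detection p-values, adds an offset of 16 and returns log2 values. The offset draws the folds of dim genes towards 1. Probes with a detection p under 0.05 on at least 4 of the 8 arrays were kept, which left 9433. Knockout and control were compared with lmFit and eBayes with an intensity trend, with no block or covariate, and p-values were adjusted by the Benjamini-Hochberg method over the kept probes with a threshold of 0.05. Where every array of a group had a detection p of 0.05 or more, the fold is a lower bound, the mean of the brighter group against the dim group's mean of the higher of the probe's own value and the lowest value among the probes above background on that array. A fold without such a bound is 2 to the power of the difference between the group means of log2 values. Errors after ± are standard deviations over the 4 arrays of a group.

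Gene lists were tested with camera, with a preset correlation of 0.01 between genes, on 1 probe per gene, the kept probe with the highest mean signal, and adjusted over the 25 lists with at least 3 measured genes. Before the data were examined, 29 lists were fixed, 17 of pathways or of the neighbourhood of Il15ra and 12 of cell type markers, with 491 entries, of which 438 had a probe and 268 were kept. A few genes stand in more than 1 list. A gene with several probes can therefore have another value in its list than on its probe with the smallest p, as for H2-Ab1. The genes named were also fixed by rule before the data were examined. They are Il15ra, the 12 higher and 12 lower genes with the largest absolute log2 difference among probes with 1 symbol, an adjusted p under 0.05 and no overlap between the groups, with 1 probe per gene, that with the smallest p, and clone names left out, and up to 4 members of each list with the smallest p. Other genes in the text were chosen after their values were seen.

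The alternatives tried were no background correction, an offset of 50, median scaling, cyclic loess, the authors' normalised values, no filter on dim probes, a detection p under 0.01 on all arrays, eBayes without the trend or with robust estimation, array weights, the replicate number as a block, a threshold of 0.01, a minimum log2 difference of 1, camera with an estimated correlation, fry, the mean over all probes of a gene, and each array left out in turn. Added after the data were seen were the number of detected probes per array as a covariate and a fit without the 3 arrays with the fewest detected probes. All 35 splits of the 8 arrays into 4 and 4 were fitted in the same way.

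The test was checked on simulated data with the same 9433 probes, of which 200 were changed by known amounts. With independent noise it recovered 28% of probes changed by a log2 difference of 1, 58% at 2, 90% at 3 and 96% at 4, and called 10 unchanged probes. With the strongest component of the variation within groups kept as it is in these arrays, it recovered 4%, 52%, 92% and 96% and called 0 unchanged probes. With that component and the number of detected probes as a covariate it recovered 74%, 96%, 100% and 100% and called 4 unchanged probes. The component was taken from deviations around the group means, so by construction it adds no difference between knockout and control. These simulations therefore do not show whether such structure creates false calls when it lies unevenly over the groups.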

Results

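Gene expression was measured in primary mouse hepatic stellate cells, the retinoid-storing pericytes of the liver that turn into matrix-producing myofibroblasts in injury and in culture. Cells came from mice lacking the alpha chain of the interleukin-15 receptor (IL15Ra-knockout, 4 samples) and from wild-type control mice of the same mixed background (4 samples), and each sample was hybridised to 1 array. All mice are labelled female, a label that the Y-linked probes described at the end put in question. The receptor alpha chain binds interleukin-15 and presents it to neighbouring cells. The series asks whether the receptor governs how fibrogenic these cells are, and the design holds a single comparison, knockout against control. Each array gave a signal for 25697 probes, with a median between 113.6 and 149.8 per array, and 9433 probes were kept for testing. The number of probes above background ranged from 6760 on control 3 to 10516 on knockout 2, and was 8812 ± 1300 (SD, n = 4) in the knockout and 8983 ± 1495 (n = 4) in the control arrays, with a two-sided exact permutation p of 0.914. Knockout 1 (7765 probes), knockout 4 (7830) and control 3 (6760) had fewer probes above background than the other 5 arrays, and these 3 arrays stood apart on the first principal component, which held 78.2% of the variance. The second component, with 11% of the variance, had negative scores for the 4 knockout and positive scores for the 4 control arrays. The number of arrays limits the precision of every value given here.

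**Figure D1:**
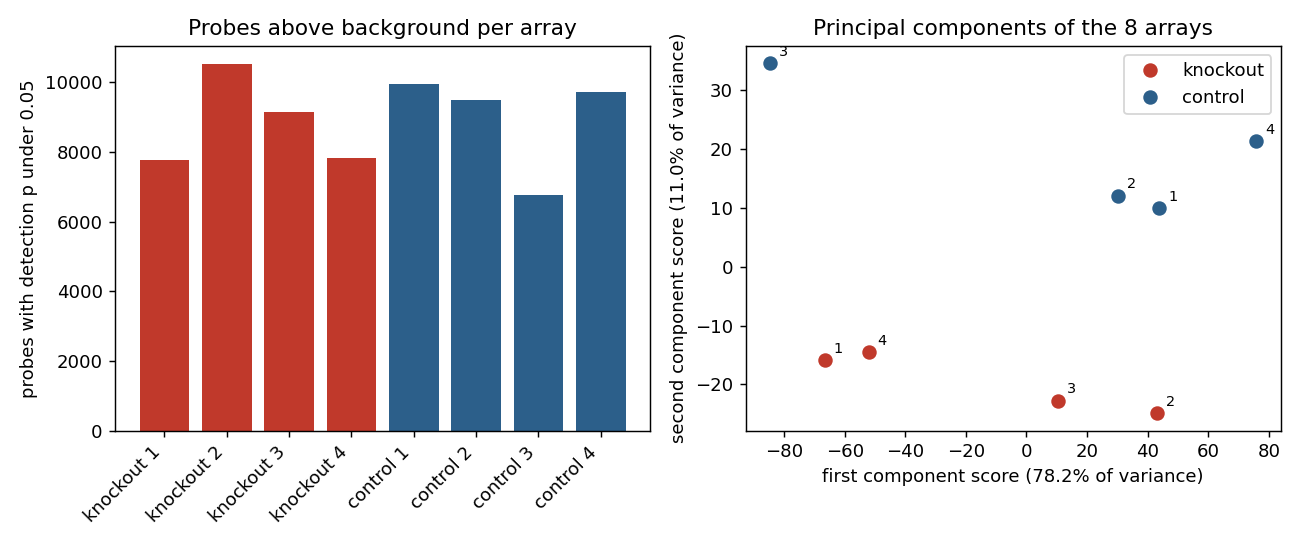
The left panel plots the number of probes with a detection p under 0.05 for each of the 8 arrays as bars, and the right panel plots each array's scores on the first principal component (78.2% of variance, horizontal axis) and the second (11%, vertical axis), with the replicate number beside each point. Control 3, knockout 1 and knockout 4 have the fewest detected probes and lie at the low end of the first component, while the second component has the 4 knockout arrays below and the 4 control arrays above 0.

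The targeted gene, Il15ra, could not be followed on these arrays. None of its 4 probes was above background on any of the 8 arrays, and the lowest detection p of any of them was 0.178. The mean of the 4 probes was 4.69 ± 0.03 on the log2 scale in the knockout and 4.70 ± 0.03 in the control arrays (SD, n = 4 each), so Il15ra checks nothing about the labels here. Il15 itself was measured on all 8 arrays, at 9.003 ± 0.50 in the knockout and 8.95 ± 0.28 in the control cells, with a limma adjusted p of 0.963.

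Genes for major histocompatibility complex (MHC) class II, the molecules that present antigen to helper T cells, were lower in the knockout than in the control cultures. Each value is for a whole culture, so knockout cells and control cells here mean all cells of a culture. A difference cannot be assigned to the stellate cells among them. H2-Eb1 was 34.6-fold, H2-Ab1 20.0-fold and H2-Aa 9.44-fold lower in the knockout cells. The protease genes Ctsc and Ctse were about 14.98-fold and 15.92-fold lower, and the collagenase gene Mmp13 was 3.48-fold lower. In the other direction, the collagen chain gene Col1a2 was about 3.57-fold higher, the DNA replication gene Mcm6 was 7.41-fold higher, and the gene for Grem1, a secreted antagonist of bone morphogenetic proteins, was 8.19-fold higher in the knockout cells. Cell cycle genes were higher as a group (camera adjusted p = 6.53e-06, adjusted p = 0.0536 with an estimated correlation), and groups of chemokine (0.000153 and 0.0306), immediate early (1.53e-05 and 0.0285) and interferon-gamma target genes (0.000202 and 0.0322) were lower, while none of 14 measured genes of fibrogenic activation passed the test.

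With limma and Benjamini-Hochberg adjustment over the 9433 probes, 50 probes had an adjusted p under 0.05, of which 22 were higher and 28 lower in the knockout arrays. Of these probes, 46 named 42 genes and 4 are unnamed here. The 4 knockout values lay apart from the 4 control values at all 50, and 48 differed at least 2-fold. Over all kept probes the groups did not overlap at 474 (5.02%), where chance gives 2.86% on average. Probes vary together on these arrays, so the share can lie far from that average by chance, and the difference was not tested. An unadjusted p under 0.05 was reached by 595 probes.

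Among the genes lower in the knockout cells, H2-Aa had the smallest p, at 10.27 ± 0.32 on the log2 scale in the knockout against 13.51 ± 0.12 in the control arrays (SD, n = 4 each, adjusted p = 0.000115). H2-Eb1 lay at 6.06 ± 1.26 against 11.17 ± 1.44 (adjusted p = 0.0302) and was above background on 2 of the 4 knockout arrays, and its log2 difference of -5.11 ranged from -5.77 to -3.81 over the alternatives. H2-Ab1 lay at 7.01 ± 0.91 against 11.33 ± 1.00 (adjusted p = 0.0135). Ctsc, the lysosomal dipeptidyl peptidase that activates granule serine proteases, lay at 9.74 ± 0.46 against 13.65 ± 0.13 (adjusted p = 0.000115), and its 3 probes gave log2 differences between -4.21 and -3.91. Ctse, an endosomal aspartic protease of antigen-presenting cells, lay at 5.90 ± 0.39 against 9.89 ± 0.14 (adjusted p = 0.000329). Hal, which encodes histidine ammonia-lyase, was 18.7-fold lower, and Gdpd3, which encodes a lysophospholipase D, was 17.5-fold lower, both with an adjusted p of 0.000321. Klk8, a secreted serine protease gene, was not above background on any knockout array and was at least 8.77-fold lower there (adjusted p = 0.00192). Cap1, which encodes an actin-binding protein, was 8.32-fold lower. Tubgcp5, a gene of the gamma-tubulin complex, was not above background on any knockout array and was at least 4.29-fold lower on 1 probe and at least 1.51-fold on its other kept probe. The remaining members of the 12 were Rasgrp1, an activator of Ras, which was 5.81-fold lower, and Fgd2, an activator of Cdc42, which was 5.32-fold lower. On the knockout arrays H2-Ab1 and Hal were above background on 3 of 4, Ctse on 2 and Rasgrp1 on 1.

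Among the genes higher in the knockout cells, Pafah1b2, which encodes a catalytic subunit of a platelet-activating factor acetylhydrolase, lay at 8.23 ± 0.15 on the knockout arrays and was not above background on any control array, a difference of at least 5.44-fold (SD, n = 4, adjusted p = 0.000321). The homeobox gene Nkx2-3 was likewise not above background on any control array and was at least 5.39-fold higher (adjusted p = 0.00417). Bounds of the same kind were at least 3.55-fold for Aoc3, an amine oxidase and adhesion protein gene, at least 3.55-fold for the microfibril gene Mfap5, at least 3.34-fold for Exosc9 of the RNA exosome, at least 2.98-fold for the insulin-like growth factor binding protein gene Igfbp2, and at least 2.07-fold for Yipf4. Each of the genes with such a bound in this direction had 1 kept probe. The mice are of mixed background, and probe mismatches between mouse strains were not tested for any gene, higher or lower. Mcm6 lay at 12.48 ± 0.20 in the knockout and 9.59 ± 0.79 in the control arrays (SD, n = 4 each, adjusted p = 0.00826), while its other kept probe gave a log2 difference of 1.21 and did not pass. Grem1 lay at 9.57 ± 1.12 against 6.54 ± 0.17 (adjusted p = 0.0447). Adam23 was 10.2-fold higher, the Golgi GTPase gene Rab6b was 6.57-fold higher, and the guidance ligand gene Slit2 was 4.97-fold higher, with adjusted p-values of 0.0331, 0.00270 and 0.0195. On the control arrays Grem1 was above background on 3 of 4, Adam23 on 2, and Rab6b and Slit2 on 1 each. These folds are on a scale to which an offset of 16 signal units was added, so they understate the change of dim genes. They can also understate it where a group lies near the top of the scale, as for Ctsc and H2-Aa in the control and Col1a2 in the knockout arrays, although the control means of the other 2 Ctsc probes, 10.56 and 11.40, lay lower and gave similar differences.

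**Figure D2:**
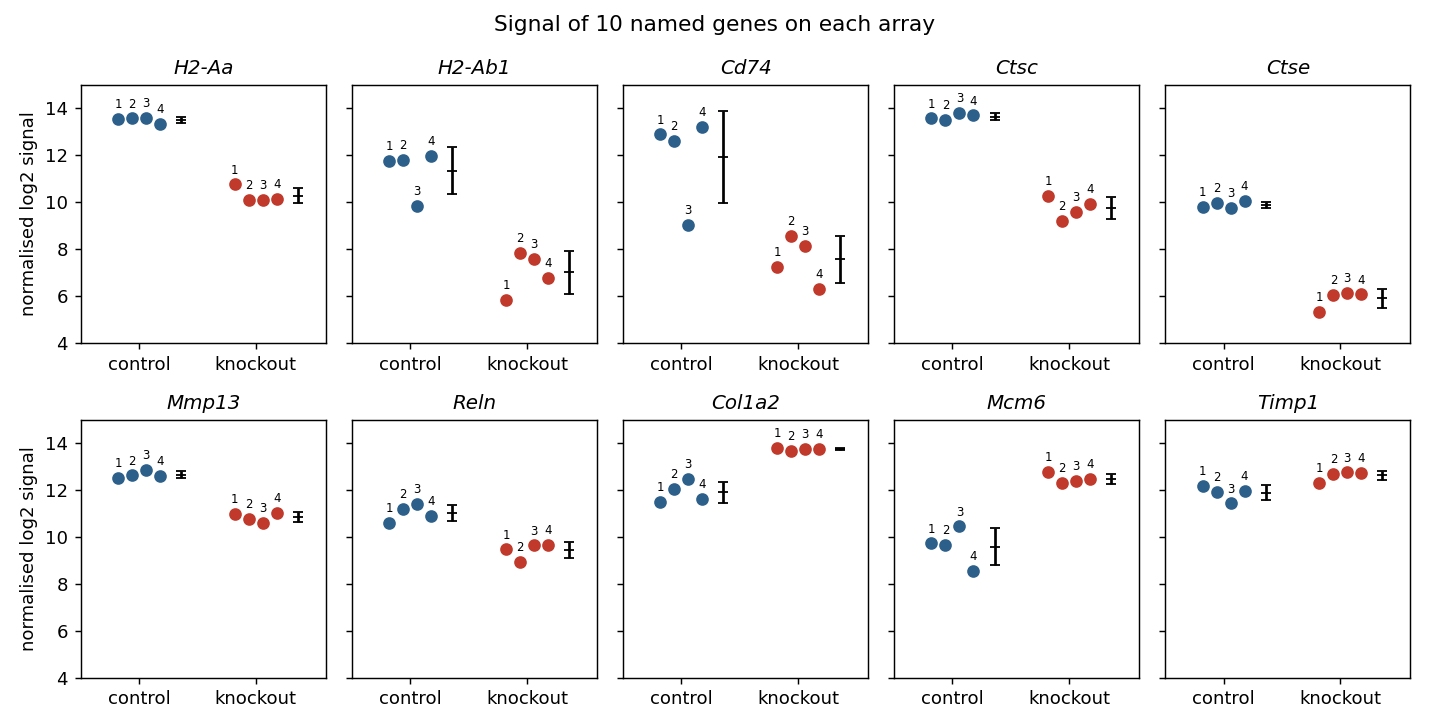
Each panel plots the normalised log2 signal (vertical axis) of 1 gene on the 4 control and 4 knockout arrays, with the replicate number above each point and the mean ± SD of the group as a bar beside it (n = 4 per group). H2-Aa, H2-Ab1, Ctsc, Ctse, Mmp13 and Reln were lower, and Col1a2 and Mcm6 higher, in the knockout arrays with an adjusted p under 0.05, while Cd74 (adjusted p = 0.103) and Timp1 (0.174) did not pass.

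The number of passing probes depended on single arrays and on the array structure. It was 24 without knockout 3, 22 without knockout 4, 24 without control 1, 20 without control 2, 152 without control 3 and 24 without control 4. Of the 24 genes named above with the largest differences, 12 passed in all 8 fits that left out 1 array, namely Pafah1b2, Nkx2-3, Mcm6, Rab6b, Mfap5, Hal, Gdpd3, Klk8, Ctse, Ctsc, H2-Aa and Cap1. The other 12 lost the call in at least 1 such fit (H2-Eb1, Adam23, Aoc3, Yipf4, Rasgrp1 and Fgd2 in 6, Grem1 and Slit2 in 5, H2-Ab1 in 4, Exosc9 and Tubgcp5 in 3 and Igfbp2 in 2), with 6 genes lost without knockout 1, 3 without knockout 2, 9 without knockout 3, 10 without knockout 4, 10 without control 1, 11 without control 2, 0 without control 3 and 9 without control 4. With the number of detected probes per array as a covariate, a fit chosen after the data were seen, 670 probes passed, 402 higher and 268 lower, and these included all 50. Without knockout 1, knockout 4 and control 3, also chosen after the data were seen, 185 passed, 92 higher and 93 lower, again with all 50 among them. Median scaling gave 60 higher and 48 lower probes and cyclic loess 52 higher and 43 lower, against 22 and 28 with quantile normalisation. The median log2 difference of all kept probes was 0.03 with quantile normalisation and -0.10 with median scaling, and differences are to be read relative to it.

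The gene groups tested were fixed before the data were examined. Of 29 lists, 25 had at least 3 measured genes, and 11 of these passed limma's camera test with an adjusted p under 0.05, 3 higher and 8 lower in the knockout cells. The test assumed a correlation of 0.01 between genes. With a correlation estimated per list, 4 lists still passed, namely dendritic cells and MHC class II, MHC class I and interferon-gamma targets, chemokines, and immediate early genes. With an estimated correlation and the number of detected probes as a covariate, only the MHC class II list passed (adjusted p = 0.0223), and the other 3 did not (0.0642 each). Without knockout 1, knockout 4 and control 3 all 4 calls were lost (0.0970 for MHC class II, 0.178 for interferon-gamma targets, 0.176 for chemokines and 0.131 for immediate early genes), and with the replicate number as a block as well (0.104 for MHC class II and 0.137 for the other 3). With the authors' normalised values all 4 passed (0.00777, 0.0329, 0.0317 and 0.0280), as did cell cycle, quiescence and endothelial genes (0.0492 each). With fry's directional test, 7 lists passed. Its mixed test asks whether members differ in either direction. Among the lists that camera did not call, it passed matrix remodelling (adjusted p = 4.91e-07), retinoid and lipid storage (0.00133), collagens (0.00456) and NK cells (0.0352). The other lists that camera did not call had a mixed adjusted p over 0.05.

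The list of dendritic cell and MHC class II genes was lower, with a median log2 difference of -3.24 (camera adjusted p = 8.03e-12, and adjusted p = 0.00719 with an estimated correlation). Its median was -0.68 without the filter on dim probes and -2.44 without the 3 arrays with the fewest detected probes. Of its 7 measured genes, 3 fell, namely H2-Aa, H2-Eb1 and H2-Ab1, and 5 were lower when adjusted over the list alone. The further pair were Cd74, the MHC class II invariant chain, at 7.57 ± 1.00 in the knockout and 11.94 ± 1.95 in the control arrays (SD, n = 4 each, adjusted p = 0.103 over all probes), and Ciita, the transactivator of MHC class II genes, which was not above background on any knockout array and was at least 1.67-fold lower (adjusted p = 0.193). The list of MHC class I and interferon-gamma targets was lower too (median -0.41, camera adjusted p = 0.000202, adjusted p = 0.0322 with an estimated correlation). None of its 10 measured genes passed over all probes, and 2 were lower when adjusted over the list alone. These were the transcription factor gene Irf1, at 11.35 ± 0.24 against 12.12 ± 0.26, and the guanylate-binding protein gene Gbp2, at 8.04 ± 0.22 against 8.99 ± 0.17 (SD, n = 4 each). The other kept probe of Irf1 had a log2 difference of -1.75, with a standard error of 1.02. Tap2 had a log2 difference of -0.47 and Psmb9 of -0.36, with adjusted p-values of 0.750 and 0.913. The interferon-stimulated genes, which respond mainly to type I interferon, did not pass as a list (median -0.20, camera adjusted p = 0.0679), with 0 of 11 genes past the threshold and 1 lower, Gbp2, when adjusted over the list alone. In this list Bst2 had a log2 difference of 0.72, Rsad2 of -0.48 and Mx2 of -0.40.

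Chemokine and inflammation genes were lower as a list (median -0.60, camera adjusted p = 0.000153, adjusted p = 0.0306 with an estimated correlation), with a median of -0.14 among genes with a detection p under 0.01 on all arrays. Of 20 measured genes 1 fell, the T cell and NK cell chemokine Ccl5, at 5.605 ± 0.42 in the knockout against 7.55 ± 0.27 in the control arrays (SD, n = 4 each, adjusted p = 0.0314), and above background on 2 of 4 knockout arrays. Adjusted over the list alone, 2 genes were lower, Ccl5 and the neutrophil chemokine Cxcl1 (log2 difference -1.33), and 1 was higher, the acute-phase gene Saa3 (1.00). The cytokine gene Il1b had a log2 difference of -1.85 and an adjusted p of 0.401. The call of Ccl5 was lost without each of the arrays except control 3, with adjusted p-values of 0.0927, 0.0968, 0.125 and 0.0943 without knockout 1, 2, 3 and 4, and of 0.125, 0.162 and 0.0716 without control 1, 2 and 4. Immediate early and dissociation-response genes were lower as a list (median -0.44, camera adjusted p = 1.53e-05, adjusted p = 0.0285 with an estimated correlation), with 13 of 14 measured genes below 0 and none past the threshold over all probes or over the list alone. Junb had a log2 difference of -1.15, Fosb of -1.66, Egr1 of -0.36 and Dusp1 of -0.34.

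Cell cycle genes were higher as a list (median 0.71, camera adjusted p = 6.53e-06), and this call was lost with an estimated correlation (adjusted p = 0.0536). Of 14 measured genes 1 rose, the replicative helicase gene Mcm6, and 2 were higher when adjusted over the list alone, Mcm6 and the mitotic kinase gene Plk1. Plk1 lay at 10.38 ± 0.68 in the knockout and 7.93 ± 0.98 in the control arrays (SD, n = 4 each, adjusted p = 0.114 over all probes). Mcm5 had a log2 difference of 0.70 and Pcna of 0.27, with adjusted p-values of 0.548 and 0.600. The list had 12 of its 14 genes above 0.

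Genes of fibrogenesis did not move as a block. Of 11 measured collagen genes 1 rose, Col1a2, at 13.74 ± 0.04 in the knockout and 11.90 ± 0.45 in the control arrays (SD, n = 4 each, adjusted p = 0.00478). Col4a1 had a log2 difference of -0.72, Col5a2 of -0.99 and Col15a1 of 0.86, none past the threshold, and the collagen list had a camera adjusted p of 0.912. Col1a1, the partner chain of Col1a2 in type I collagen, had a log2 difference of 0.06 with a standard error of 0.81. None of 14 measured genes of fibrogenic activation passed (median -0.11, camera adjusted p = 0.695). Among them Timp1, the tissue inhibitor of metalloproteinases, had a log2 difference of 0.74, with an adjusted p of 0.174 over all probes and 0.0371 over the list alone. Ccn2 had a difference of -0.56, Loxl1 of 0.40 and Pdgfrb of -0.83. Acta2, the smooth muscle actin of activated stellate cells, lay at 14.18 ± 0.04 in the knockout and 14.14 ± 0.05 in the control arrays, at the top of the array's scale, where a change would be hard to see. Of 17 measured matrix remodelling genes 1 fell, Mmp13, at 10.85 ± 0.20 against 12.65 ± 0.15 (SD, n = 4 each, adjusted p = 0.000863), and its other kept probe had a log2 difference of -1.86 without passing. Col1a2 and Mmp13 passed in all 8 fits that left out 1 array. Adjusted over the list alone Mmp13 was lower and Timp1 higher, and the list had a camera adjusted p of 0.456. Plau had a log2 difference of 1.04 and Mmp23 of 0.51.

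The list named for targets of transforming growth factor beta was lower (median -0.46, camera adjusted p = 0.000638), with 11 of 12 measured genes below 0. None passed the threshold over all probes or the list alone. The list also holds components of the pathway (Tgfb2, Tgfb3, Tgfbr1, Tgfbr2 and Smad3), so it does not measure the pathway's output alone. The estimated correlation between its genes was 0.548, and with it the call was lost (adjusted p = 0.345). Id2 had a log2 difference of -0.25, Tgfbi of -0.54 and Id3 of -0.79. Genes of stellate cell quiescence were lower as a list (median -0.21, camera adjusted p = 0.00224, adjusted p = 0.0536 with an estimated correlation). Only 7 of the 19 listed genes were measured. Lrat, Gfap, Ngfr, Lhx2, Hand2, Pth1r, Vipr1, Rgs5 and Bambi were above background on 0 arrays of either group, so the result speaks only for the genes measured. Of 7 measured genes 1 fell, Reln, the secreted glycoprotein that marks stellate cells in liver, at 9.42 ± 0.34 against 11.03 ± 0.35 (SD, n = 4 each, adjusted p = 0.0289). The call of Reln was lost without each of the arrays except control 3, with adjusted p-values of 0.0851, 0.0589, 0.0949 and 0.0943 without knockout 1, 2, 3 and 4, and of 0.0566, 0.157 and 0.0829 without control 1, 2 and 4. The proteoglycan gene Dcn had a log2 difference of -0.21 on a probe near the top of the scale and of -0.95, with a standard error of 0.76, on a dimmer one, Tcf21 of -0.44 and Ecm1 of -0.50. Retinoid and lipid storage genes did not pass (0 of 7, camera adjusted p = 0.912), and their median of -0.19 and mean of 0.16 differed in sign. Aldh1a1, a retinaldehyde dehydrogenase gene, lay at 8.65 ± 0.50 in the knockout and 6.74 ± 0.82 in the control arrays, with an adjusted p of 0.162 over all probes and 0.0163 over the list alone. Scd1 had a log2 difference of 0.54, Rarb of -0.42 and Plin2 of -0.31.

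**Figure D3:**
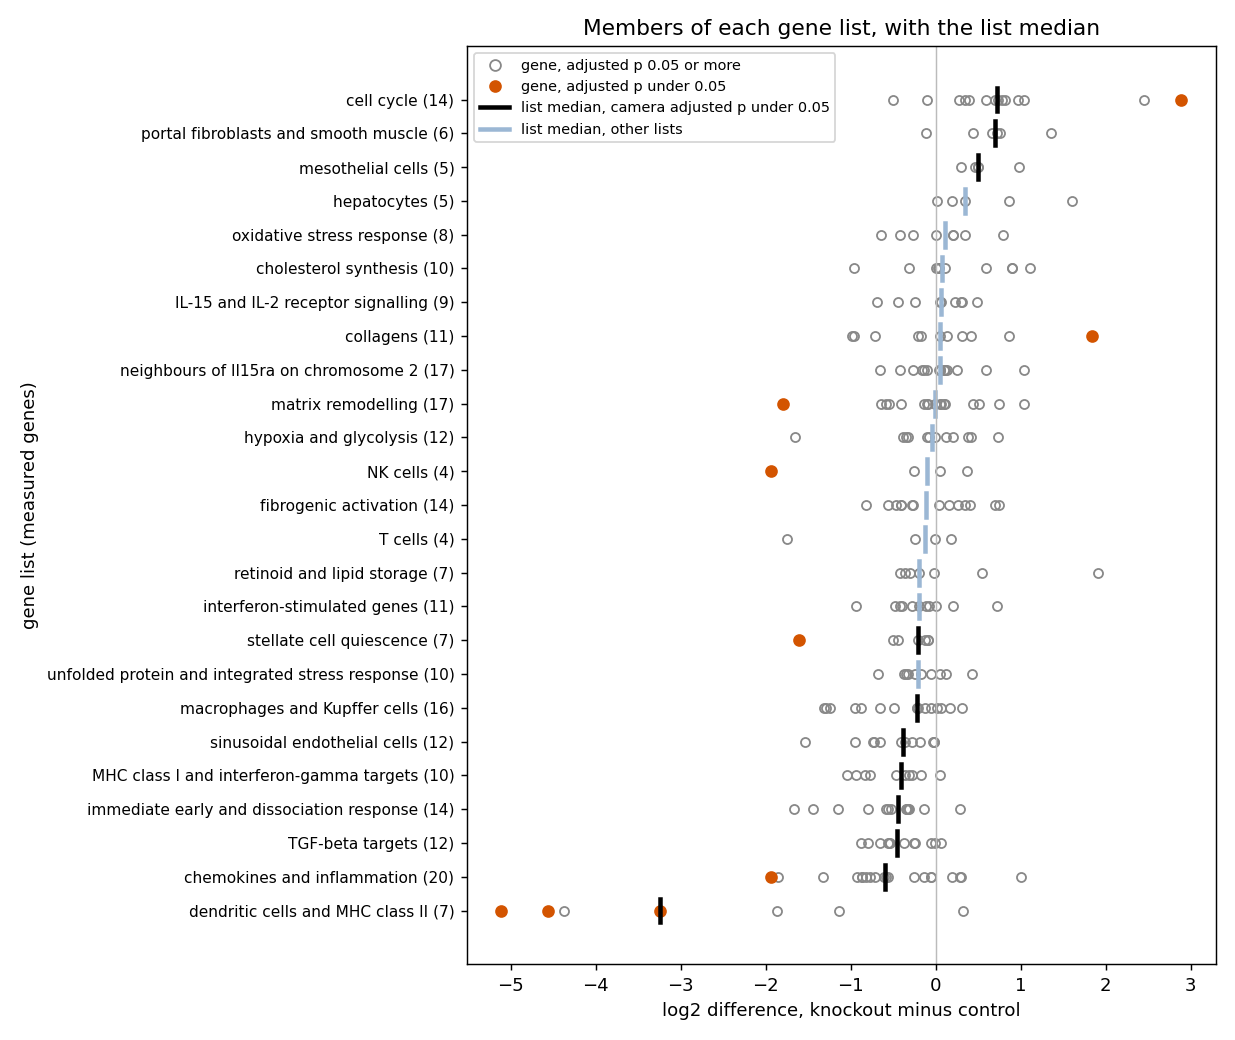
Each row is a gene list with its number of measured genes in brackets, each circle is the log2 difference (knockout minus control, horizontal axis) of 1 gene, and the vertical tick is the list's median. Filled circles are genes with an adjusted p under 0.05, and black ticks mark the 11 lists that passed camera, from dendritic cells and MHC class II at -3.24 to cell cycle at 0.71.

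Of the lists of markers of other liver cells, 4 passed with the preset correlation, besides that of dendritic cells and MHC class II, and none of these 4 passed with an estimated one. Macrophage and Kupffer cell markers were lower as a list (median -0.22, camera adjusted p = 0.0201), with 0 of 16 genes past the threshold over all probes or the list alone, and the call was lost with an estimated correlation (adjusted p = 0.0897), with median scaling (0.202) and without control 3 (0.0503). Clec4f had a log2 difference of -1.29, Vsig4 of -0.49, Timd4 of -0.88 and Lyz2 of 0.17. Sinusoidal endothelial markers were lower (median -0.39, camera adjusted p = 0.000577), with all 12 measured genes below 0 and none past the threshold over all probes or the list alone, and this call was lost with an estimated correlation (adjusted p = 0.0536). Lyve1 had a log2 difference of -1.54, Emcn of -0.96, Stab2 of -0.66 and Pecam1 of -0.74. Mesothelial markers were higher (median 0.49, camera adjusted p = 0.0164), with all 5 measured genes above 0 and none past the threshold over all probes or the list alone. That call was lost with an estimated correlation (adjusted p = 0.0897), with median scaling (0.0805), without knockout 2 (0.0604) and without control 3 (0.247). Msln had a log2 difference of 0.98, Wt1 of 0.49, Gpm6a of 0.46 and Lrrn4 of 0.50. Portal fibroblast and smooth muscle markers were higher (median 0.69, camera adjusted p = 0.0106), with 0 of 6 genes past the threshold over all probes and 1, Thy1, over the list alone. This call was lost with an estimated correlation (adjusted p = 0.151), with array weights (0.221) and without control 3 (0.246). Thy1 lay at 11.88 ± 0.11 in the knockout and 11.21 ± 0.33 in the control arrays (SD, n = 4 each), and Fbln2, Dpt and Eln had log2 differences of 0.75, 1.36 and 0.72.

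The other cell type lists did not pass. Of 4 measured NK cell genes 1 was lower, Ccl5, which is also a chemokine list member (camera adjusted p = 0.111), and Prf1, Klrb1c and Il2rb had log2 differences of 0.37, -0.26 and 0.05. Other listed NK cell genes, Ncr1, Klrk1, Klrd1, Klre1, Klrg1, Gzma, Gzmb, Nkg7, Eomes and Tbx21, were above background on 0 arrays of either group. These values are therefore no readout of NK cells in the cultures. None of 4 T cell genes passed over all probes (camera adjusted p = 0.197), and the T cell genes Cd3g, Cd4, Cd8a and Cd2 were above background on 0 arrays. Cd3d was lower when adjusted over the list alone, by at least 1.69-fold, since it was not above background on any knockout array, while Il7r, Cd3e and Lat had log2 differences of 0.18, -0.25 and -0.01. None of 5 hepatocyte genes passed over all probes (median 0.35, camera adjusted p = 0.0886), and Ahsg, with a log2 difference of 1.6004, was higher over the list alone. Ttr, Trf and Serpina1a had log2 differences of 0.86, 0.35 and 0.19. B cells, neutrophils and cholangiocytes had 2 measured genes each and erythroid cells 0, so these lists were not tested. None of these genes passed, with log2 differences of -0.22 for Cd79b, 0.18 for Cd22, -0.60 for S100a8, -0.26 for Csf3r, 1.38 for Krt18 and 0.57 for Krt7.

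Genes of interleukin-15 and interleukin-2 receptor signalling did not pass as a list (0 of 9 past the threshold over all probes or the list alone, camera adjusted p = 0.664). The direction of the test was opposite to the sign of their median of 0.06 and mean of 0.00. Il2ra, Jak3, Stat5b, Socs1 and Bcl2l1 were too dim to be kept, above background on at most 2 arrays, so the list covers only part of the pathway. Socs3 had a log2 difference of -0.45, Mcl1 of -0.25, Cish of 0.48 and Stat3 of 0.29. Genes that neighbour Il15ra in the GRCm38.p6 annotation had 0 of 17 past the threshold (median 0.05, mean 0.04, test direction lower, camera adjusted p = 0.817). Ccdc3 had a log2 difference of -0.65, Mcm10 of 1.03, Cdc123 of 0.59 and Atp5c1 of 0.13. Cholesterol synthesis genes did not pass (0 of 10 over all probes, median 0.07, camera adjusted p = 0.197), and 4 were higher and 1 lower over the list alone. Of these, Idi1, Hsd17b7 and Lss had log2 differences of 0.59, 0.89 and 1.11, and Insig1 one of -0.97 on the probe used, with its 3 probes ranging from -0.97 to 0.45. The unfolded protein and integrated stress response (0 of 10, median -0.21, camera adjusted p = 0.456), hypoxia and glycolysis (0 of 12, median -0.05, 0.739) and the oxidative stress response (0 of 8, median 0.10, 0.518) did not pass either, and none of their genes passed over the list alone. Among their members Chac1 had a log2 difference of 0.43, Atf3 of -0.68, Dnajb9 of -0.33 and Herpud1 of 0.12. Adm, a hypoxia-responsive peptide hormone gene, had a difference of -1.66 (adjusted p = 0.332), Tpi1 one of 0.20, Egln3 one of 0.73 and Pfkl one of 0.42. Prdx1, Txnrd1, Srxn1 and Cat had log2 differences of 0.20, 0.34, 0.79 and -0.42. Some genes of the lists gave other values on their other kept probes, with ranges of -0.07 to 0.79 for Srxn1, -0.07 to 0.20 for Prdx1, -0.28 to 0.12 for Herpud1, -0.08 to 0.42 for Pfkl, 0.01 to 0.20 for Tpi1, -0.07 to 0.17 for Lyz2, 0.18 to 0.84 for Il7r, 0.19 to 0.81 for Serpina1a and 0.10 to 0.46 for Gpm6a.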

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

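Of the tests described here, the spread between probes of a gene and the counts over splits of the arrays were set before their results were seen, and the others were chosen afterwards. A single array far from the other 3 of its group was looked for in 248 sets of 4 arrays, and 17 were found where chance alone gives about 12.4, at 1 in 20.

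On control 3, 6760 probes were above background, against 9490 to 9961 on the other control arrays. The same array was lowest among the controls for the MHC class II genes Cd74 (9.03 on the log2 scale, others 12.60 to 13.22) and H2-Ab1 (9.84, others 11.75 to 11.96), and for Fosb (7.76), Ecm1 (8.11) and Col15a1 (4.73), and highest for Klrb1c (6.93) and Plin2 (6.69). Among the other control arrays, Mcm5 was low on control 4 (9.63), and Exosc9 on control 1 (4.92) and Rab6b on control 2 (5.68) were high, at levels near background. Among the knockout arrays, knockout 1 was highest for H2-Aa (10.75, others 10.10 to 10.12) and lowest for Ctse (5.31), Timp1 (12.31) and S100a8 (7.80). Knockout 4 was lowest for Prdx1 (13.89) and highest for Dusp1 (13.65).

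Knockout 1, knockout 4 and control 3 stood apart from the other 5 arrays in the number of detected probes and on the first principal component. Genotype does not account for this, since control 3 had the lowest score of all arrays (-84.7), below every knockout array. A different mix of cells in the 3 cultures, as the whole cause, would tend to move all probes of a gene together, but in 1301 genes with several kept probes the median spread between probes of a gene was 0.975 in the contrast of these 3 with the other 5 arrays, against 0.288 between knockout and control. These spreads are not scaled to the size of each contrast, and probes near background or the top of the scale need not move together. The result therefore argues against a cell mix without excluding it. Loss of short transcripts could not be decided, since the 67 probes of ribosomal protein genes lay at a median of -0.70 relative to all kept probes, between the bounds set for and against it. A difference in RNA quality or labelling between these samples therefore stays open, as a hypothesis.

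MHC class II genes were lower in the knockout arrays, with a median log2 difference of -4.37 over 5 genes. The 3 arrays do not account for this, since the median was -3.96 without them and all 5 genes passed. A lower share of macrophages as a whole would lower their markers alike, but 16 such markers, none of which is in another list, had a median of -0.22 (range -1.31 to 0.31). The 12 of them dimmer than H2-Aa in the control arrays had a median of -0.57. H2-Aa itself lay near the top of the scale there, at 13.51, and some of the 12, such as Vsig4 at 13.09, may be compressed too. Fewer dendritic cells, which a density gradient need not remove, and a lower MHC class II level within the cells cannot be told apart, since 2 other dendritic cell markers were measured, with a median of -0.41. With the number of detected probes as a covariate these markers went in opposite directions, Itgax at -1.04 and Siglech at 0.24. Probe mismatches between mouse strains were not tested, and the genotype stays open as the biological explanation.

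As many probes as the 50 between knockout and control were called by 3 of the 35 splits of the 8 arrays into 4 and 4, the real one included, so chance cannot be excluded for this count. The other 2 splits called 5321 and 2735 probes, and both put knockout 1, knockout 4 and control 3 together, with knockout 3 or control 2 as the fourth array, which points to the structure of the arrays described above, although the 3 further splits that put these 3 arrays together called 0. With the number of detected probes as a covariate, the real split called 670 probes and the highest of the other splits 0. In that fit 1 of 35 splits, the fewest that this design allows, gave as many. Since the covariate was chosen after the data were seen, this does not exclude chance. The splits also cannot separate genotype from any other difference shared by the 4 samples of a group. For the gene lists 2 of 35 splits gave as many as 11, with 11 as the highest of the other splits, so chance cannot be excluded for the number of lists.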

How the results depend on the processing

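The covariate and the fit without 3 arrays were chosen after the data were seen. Against 50 passing probes, median scaling gave 108, cyclic loess 95, a detection p under 0.01 on all arrays 17 of 5304 probes tested, a threshold of 0.01 on the adjusted p 22, the number of detected probes as a covariate 670, and the fit without knockout 1, knockout 4 and control 3 185. All 50 were kept with the covariate and without the 3 arrays, 41 with median scaling and 49 with cyclic loess. Array weights gave 3632, and their estimation stopped before it converged. Leaving out 1 array gave 20 (without control 2) to 152 (without control 3). No background correction, an offset of 50, the authors' normalised values, no filter, eBayes without trend or with robust estimation and a minimum log2 difference of 1 gave 44 to 48. Against 11 passing lists, an estimated correlation gave 4 and fry's directional test 7, leaving out 1 array gave 8 to 14, and the other settings gave 9 to 12. Il15ra had a mean log2 difference of 0.051 with median scaling against -0.015, both among probes below background. All 24 genes with the largest differences kept their direction in every setting, and with the covariate and without the 3 arrays all 24 passed. Over all named genes and settings, 2240 values kept their direction and side of the threshold, 134 passed in addition, 118 no longer passed, and 21 changed sign with neither value past the threshold. Most of the 2240 belong to genes that had not passed and so had no call to lose. Among the 24 genes, calls were kept in as few as 8 of 20 settings (Aoc3) and in up to 21 of 21 (Gdpd3, Ctsc and H2-Aa). The 1 gene that reversed was Serpina1a, at -0.46 with array weights (adjusted p = 0.0317). For the lists, over the settings refitted with camera and the preset correlation, 501 values kept their side, 12 passed in addition and 7 no longer passed. That tally leaves out the estimated correlation, which kept 4 of the 11 calls, and fry's directional test, which kept 7. With both the covariate and an estimated correlation, MHC class II passed (adjusted p = 0.0223), while chemokines, immediate early genes and interferon-gamma targets did not (0.0642 each), and with an estimated correlation none of these 4 lists passed without the 3 arrays (0.0970 to 0.178) or with the replicate number as a block (0.104 to 0.137), while with the authors' normalised values all 4 passed (0.00777 to 0.0329), as did cell cycle, quiescence and endothelial genes (0.0492 each). Without the filter on dim probes the median of the MHC class II list was -0.68 against -3.24, of cell cycle genes 0.40 against 0.71, of quiescence genes -0.09 against -0.21 and of portal fibroblast markers 0.10 against 0.69, and with a detection p under 0.01 on all arrays that of chemokines was -0.14 against -0.60. Beyond the stricter filters and threshold, which test or allow fewer probes, the cause was not tested. The chip as a block was not run, since no chip is named in the tables. Probes near background limit what can be seen, since a gene such as Il15ra gives no level at all.

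With the replicate number as a block, 3 probes passed, all lower, and 11 lists. The deviations of same-numbered arrays from their group means correlated at -0.66, 0.60, -0.75 and -0.82. Of 8 arrays, 1 correlated best with its own number. These correlations can be set by the first principal component, which held 78.2% of the variance and set apart the arrays with the fewest detected probes. A weaker pairing could be hidden by it, so whether the numbers pair the samples is not decided. The labels name no shared animal, batch or day for a number.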

Other observations

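The covariate and the tests of interferon-gamma signalling and of the sex of the animals were chosen after the values were seen, as were the genes named outside the lists. Besides the genes already described, 14 further genes passed between knockout and control. Higher in the knockout cells were Pdpn, a mucin-like membrane glycoprotein of lymphatic endothelium and fibroblasts (13.42 ± 0.17 against 11.92 ± 0.32 on the log2 scale, SD, n = 4 each), the secreted chaperone gene Clu (2.76-fold), Angptl7 (1.98-fold), Lxn, an inhibitor of carboxypeptidases (1.85-fold), and Tomm22, a receptor of mitochondrial protein import (2.07-fold). The LIM homeobox gene Isl1 and Plekhb1 were not above background on any control array and were at least 1.37-fold and at least 1.96-fold higher. Lower were Clec10a, a galactose-binding lectin of macrophages and dendritic cells (10.48 ± 0.14 against 12.26 ± 0.24, SD, n = 4 each), Rerg, a Ras-related GTPase gene (3.69-fold), the secreted Wnt antagonist gene Frzb (2.38-fold), Mcee of propionate metabolism (2.06-fold), Cyp7b1, an oxysterol hydroxylase gene (3.37-fold), and Btbd11 (4.75-fold). Lypd1 was not above background on any knockout array and was at least 2.04-fold lower.

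With the number of detected probes as a covariate, further genes passed that did not without it. The largest fitted log2 differences among those above background on arrays of both groups were 2.90 ± 0.38 (SE) for the peptide hormone gene Cck, 2.52 ± 0.32 for Scara3, 2.49 ± 0.25 for the condensin gene Ncapg2 and 2.47 ± 0.23 for Abhd1. In the other direction they were -4.70 ± 0.34 for Cd74, -2.90 ± 0.25 for the chemokine receptor gene Cxcr4, -2.37 ± 0.18 for Ear10 and -2.07 ± 0.36 for H2-DMa, which loads peptides onto MHC class II. In this fit 4 of 14 cell cycle genes rose, Plk1 (2.36 ± 0.27), Mcm6, Tyms and Rrm2, and 0 fell, 4 of 14 immediate early genes fell and 0 rose, and 5 of 7 genes of the MHC class II list fell. Of 20 chemokine genes 4 fell, Ccl5, Cxcl1, Il1b and Il1rn, and 1 rose, Saa3. Of 11 collagen genes 2 rose, Col1a2 and Col15a1, and 2 fell, Col4a1 and Col5a2. Of 10 cholesterol synthesis genes 4 rose and 1 fell. Timp1 rose by 0.77 ± 0.12, and Ccn2 had a difference of -0.54 ± 0.11. Aldh1a1 rose by 1.99 ± 0.22. Markers of other cell types passed in this fit as well. Of 6 portal fibroblast and smooth muscle markers 3 rose, Thy1, Fbln2 and Dpt, and 0 fell. Of 16 macrophage markers 2 fell, Clec4f and Cd14, and 0 rose. Of 12 endothelial markers 2 fell, Lyve1 and Emcn, and 0 rose, while 0 of 5 mesothelial markers passed.

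A lower interferon-gamma signal in the knockout cultures may underlie the lower MHC class II genes, as a hypothesis. The list of MHC class I and interferon-gamma targets shares no gene with the MHC class II genes, and it was lower with an estimated correlation (adjusted p = 0.0322), but the adjusted p was 0.0642 with the covariate added and 0.178 without the 3 arrays. The test therefore does not decide.

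Several macrophage genes were among the brightest on these arrays, in both groups. By mean signal over all arrays, Lyz2 stood at percentile 99.67 of all genes, Adgre1 at 99.70 and Fcer1g at 99.98. For comparison, Dcn stood at 99.69 and Acta2 at 99.99. On the log2 scale Lyz2 lay at 13.83 ± 0.09 in the knockout and 13.66 ± 0.07 in the control arrays, Adgre1 at 13.79 ± 0.09 and 13.77 ± 0.02, Fcer1g at 14.12 ± 0.15 and 14.17 ± 0.05, and the macrophage elastase gene Mmp12 at 13.73 ± 0.08 and 13.75 ± 0.07 (SD, n = 4 each). These probes lie near the top of the scale, where a difference in macrophage content would be hard to see. The stellate cell gene Dcn lay at 13.66 ± 0.16 and 13.87 ± 0.09. The hepatocyte gene Alb was near background, at 4.64 ± 0.03 and 4.67 ± 0.04.

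The labels call the mice female, but Y-linked probes were above background on all arrays. Eif2s3y lay between 10.96 and 11.48 on the log2 scale, Kdm5d between 7.95 and 8.78 and Uty between 6.01 and 7.39. All 3 Y-linked genes were above background on 8 of 8 arrays, and the 2 Xist probes on 0 of 8, as would be the case if the animals were male. Cross-hybridisation of the Y-linked probes in female cells would need Xist above background, and with 0 such arrays this rests on probes whose response in female cells was not seen here, so the question is not decided by them.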
